A study of Arabidopsis thaliana with 8 samples.

How the data were processed

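Total RNA of whole dark-grown Arabidopsis Col-0 seedlings, 4 days old, had been labelled and hybridised to 8 Affymetrix arrays, 2 for each combination of medium (with or without lincomycin) and light (darkness or 30 min of red light). The deposited table holds 1 intensity per probe set and array, summarised by the authors with RMA (background correction, quantile normalization and median polish) per the submitters' processing notes. Software version, and whether the 8 arrays were run together, are not stated in them. The deposited values were on the linear scale, so log2 was taken before any test. Groups were read from the labels. The labels number the replicates within each group, and nothing says that the replicates came from separate cultures, so the p-values measure only the spread between these arrays.

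Of 22810 probe sets, 64 controls were left out of the tests and kept as a check of array quality, which left 22746. Genes were taken from the annotation supplied with the series: 13513 probe sets had exactly 1 listed gene, 503 had several and 8730 had none. Probe sets without a listed gene were tested and counted but could not be assigned to a gene or a list. No filter on intensity was applied in the results given first.

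Group means were fitted to the log2 values of all 8 arrays with limma 3.58.1 (lmFit and eBayes with default settings) in R 4.3.3, with 4 residual and 3.19 prior degrees of freedom and no block. The 5 comparisons were red light without lincomycin, red light with lincomycin, lincomycin in darkness, lincomycin after red light, and the interaction of light and lincomycin. All tests were two-sided, and a probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over all 22746 probe sets. Calls shared by both light comparisons, or by both lincomycin comparisons, were counted in the same direction, beside the product of the separate counts divided by the probe sets tested. Tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

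Gene lists were tested with camera of limma, with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Of 23 lists holding 445 genes, 66 genes had a named probe set, 9 lists reached the minimum of 4 measured members and were tested, and the other 14 are given by values alone. A gene with several probe sets was represented by the one with the highest mean. List members were also adjusted over the list alone. The groups, comparisons, tests, lists and the rule for named genes were fixed before the data were examined. The rule took, for each comparison, up to 10 increases and 10 decreases among called probe sets with exactly 1 gene and no overlap between the arrays of the compared groups, or, where none passed, the 3 with the lowest p. For each list it took up to 2 called members in each direction, or the member with the lowest p.

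Some choices came later. Another 13 lists, adjusted among themselves, were written after the counts per comparison and the control probe sets had been seen and before the values of their genes were seen, except for nad4L. The 6 plotted genes, the changes of probe sets with no listed gene, and the list members HAT2, FHL, GH3.3, rpoA, psbB, LHCB4.2, LHCB4.3 and AT1G74470 were chosen after their values were seen. The mean of each list per array was also fitted, and its change divided by the standard error from the spread between replicate arrays. This test and the comparisons of 4 arrays against 4 were not planned, nor were the check on shared control arrays, array quality weights and leaving out the 2 arrays with aberrant control probe sets.

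Other settings fixed in advance were shifting each array's median to a common value, quantile normalization, leaving out the dimmest 30% of probe sets (6823), raising low values to the 20th percentile (log2 3.51), eBayes with trend and robust, a replicate block, only the 4 arrays of each comparison, a further requirement of a 2-fold change, an estimated correlation for the lists, and leaving out each array in turn. With an array left out, the lone array of its group was assumed to vary like the other groups. The procedure was tested on simulated data with 200 changed probe sets, where each probe set had 1 spread, from the limma fit, in all groups. The real groups differed in spread. The standard deviation of replicate differences (log2) was 0.538 in the dark group and 0.442 in the red group. It was 0.211 in the dark lincomycin group and 0.224 in the red lincomycin group, so the shares recovered may not hold for each comparison. Of changes of 1 and 2 (log2), the procedure recovered 51% and 97% for red light without lincomycin and 49% and 99% for red light with it. For lincomycin it recovered 48% and 97% in darkness and 33% and 98% after red light. For the interaction it recovered 5% and 78%. False calls among the unchanged probe sets numbered 9, 22, 13, 5 and 4 in the same order. A first look at the counts per comparison under several settings came before this simulation.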

Results

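Transcript levels were measured on 8 Affymetrix arrays hybridised with labelled total RNA of whole Arabidopsis thaliana seedlings, wild type Col-0, grown for 4 days in darkness. The labels give a 2 by 2 design: plates with or without lincomycin, an antibiotic that blocks protein synthesis in plastids, and collection in darkness or after 30 min of red light. Each of the 4 combinations had 2 arrays, called here the dark group and the red group (both without lincomycin), the dark lincomycin group and the red lincomycin group. The labels give the lincomycin dose as 220 µg/ml in one place and 200 µg/ml in another, and which was used is not known. The number of arrays limits the precision of every value below, and all log2 changes carry the standard error of the limma fit with 2 arrays in each group.

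The median intensity per array ran from 32.0 to 36.1. Replicate arrays correlated across probe sets at r = 0.970 in the dark group, 0.995 in the dark lincomycin group, 0.979 in the red group and 0.994 in the red lincomycin group. These are correlations across probe sets, which are not independent replicates. In the dark group 1549 probe sets differed over 2-fold between the replicates, against 797 in the red group, 40 in the dark lincomycin group and 9 in the red lincomycin group. The actin control probe sets, which compare the 3' and 5' ends of the transcript as a measure of RNA degradation, gave a 41.2-fold ratio (5.36 in log2) on replicate 1 of the dark group, against 2.24-fold to 3.67-fold on the other 7 arrays. Other controls of this kind were raised far less on that array. In log2, the GAPDH ratio was 1.55, against 0.03 to 0.60 on the other 7. The ubiquitin ratio was 1.18, against 0.50 to 0.95. Hybridisation control spikes averaged 7.35 (log2 intensity) on replicate 1 of the red group, against 8.07 to 9.29 on the other 7. A gene was listed for 14016 of the 22746 probe sets tested. No gene was listed for the other 8730 (38.4%), so many genes of interest could not be named.

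**Figure D1:**
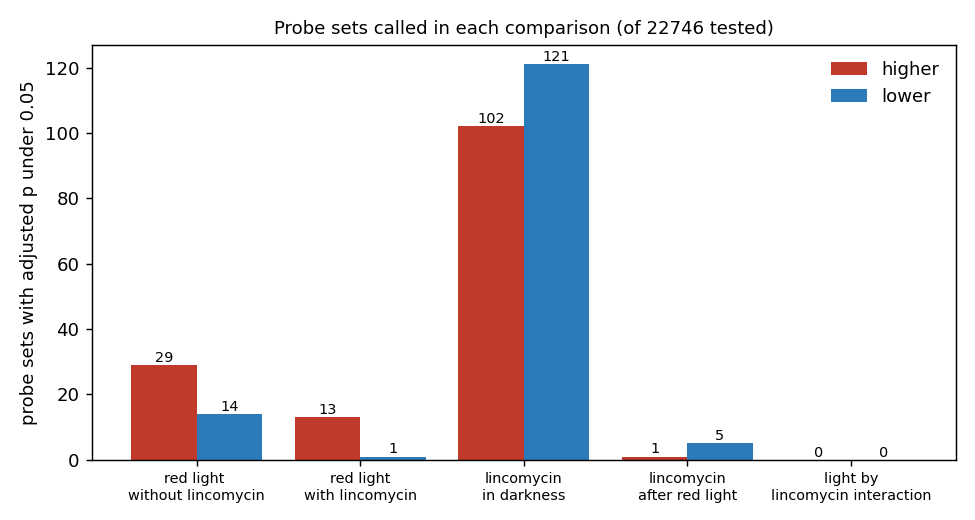
Number of probe sets past an adjusted p of 0.05 in each comparison (vertical axis), higher in red and lower in blue, of 22746 tested. Lincomycin in darkness gave 102 higher and 121 lower, lincomycin after red light 1 and 5, and the interaction 0.

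The first comparison asked what 30 min of red light did to seedlings without lincomycin. IAA29, an Aux/IAA repressor of auxin responses, fell by 2.80 ± 0.21 (log2, SE), a 6.95-fold decrease with adjusted p = 0.0121. AT3G02910 rose by 2.93 ± 0.18, a 7.60-fold increase with adjusted p = 0.00957, and AT5G15950, a S-adenosylmethionine decarboxylase of polyamine synthesis, rose by 1.86 ± 0.22 (adjusted p = 0.0402). AT1G14200 rose by 1.35 and AT3G53950 by 1.06. The genes that fell also included AT5G02580 (-1.70), AT5G53880 (2.83-fold lower) and AT2G22900 (-0.97), a galactosyltransferase gene. The protein kinase genes AT1G56720 (-1.24) and AT1G01540 (-1.11) fell as well, and the adjusted p of these genes lay between 0.0387 and 0.0474.

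Of the lists fixed beforehand, the dark- and shade-promoted PIF targets, genes activated by the phytochrome-interacting transcription factors, fell as a group after red light without lincomycin. Their median change was -0.55 over 4 measured members, with camera adjusted p = 0.00278, and adjusted p = 0.229 with an estimated correlation. IAA29 was the 1 member called over all probe sets, and 3 members were lower when adjusted over the list alone: IAA29, FHL at -0.66 and HAT2 at -0.44. The auxin-responsive genes, which share IAA29, also fell (4 members, median -0.35, camera adjusted p = 0.0420; adjusted p = 0.302 with an estimated correlation). GH3.3, an auxin-conjugating enzyme, was at -0.65, with 2 members lower when adjusted over the list alone against 1 over all probe sets. A wider list of 18 auxin genes, written after the counts had been seen, did not pass (median 0.01, -0.03 after quantile normalization, and mean -0.24, camera adjusted p = 0.319). The plastid-encoded genes rose as a group by a median of 0.43 (57 of 76 above 0, camera adjusted p = 0.00115; adjusted p = 0.580 with an estimated correlation), with 0 members called over all probe sets and 0 adjusted over the list alone by limma. Their lowest p was that of psbC, a photosystem II core protein, at 1.80 ± 0.45 (adjusted p = 0.160). The list's median stood at -0.61 (relative to the 8-array mean) on replicate 1 of the dark group, the array with the high actin ratio, against -0.09 on replicate 2.

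The other tested lists did not pass after red light without lincomycin, and lists with fewer than 4 measured members were not tested as sets. GI, a clock gene and the 1 measured member of its list, was at 1.11 ± 0.16 (adjusted p = 0.0617). LHCB4.2, a light-harvesting antenna protein, was at 1.38 (adjusted p = 0.156) and PSBY of photosystem II at 1.01 (adjusted p = 0.0800). ZAT10, of the touch, wound and rapid stress list, was at 0.74 (adjusted p = 0.109). LHCB4.2, PSBY and ZAT10 were each higher when adjusted over the list alone. The 5 nuclear photosystem and electron transport genes had a median of 0.12 (camera adjusted p = 0.220), 9 tetrapyrrole synthesis genes -0.20 (0.220), 8 plastid ribosomal protein genes 0.21 (0.278). The 5 flavonoid and anthocyanin genes were at 0.08 (0.280), 4 heat, oxidative and mitochondrial stress genes at 0.21 (0.278), and 4 cell wall loosening genes at -0.21 (0.672), whose mean was 0.04. The root marker EXPA7, an expansin of root hair cells, was at 1.14 (adjusted p = 0.133), and 2 of the 3 measured root markers were higher when adjusted over the list alone. The 3 measured reference genes were at a median of -0.37, 1 of them lower when adjusted over the list alone.

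In all, 43 of 22746 probe sets were called after red light without lincomycin in the limma fit over all 8 arrays, 29 higher and 14 lower. Exactly 1 gene was listed for 10 of them, the largest increase, 3.71, belonged to a probe set with no listed gene, and 3257 probe sets had an unadjusted p under 0.05. The share of calls that were higher was 67.4%, against 81.3% when array medians were shifted to a common value and 83.0% after quantile normalization. Leaving out replicate 2 of the dark group gave 1219 calls, replicate 1 of that group 3, and replicate 1 or replicate 2 of the dark lincomycin group 1 each. Leaving out replicate 1 of the red group gave 0 (2878 with an unadjusted p under 0.05), replicate 2 of it 1, and either array of the red lincomycin group 3. AT3G02910 kept its call without 6 of the 8 arrays, IAA29 without 2 and each of the other 8 named genes without 1. The call of the dark- and shade-promoted PIF targets was lost without replicate 2 of the dark group (adjusted p = 0.0721). That of the plastid-encoded genes was lost without replicate 1 of the dark group (0.375) or replicate 2 of the red group (0.656). That of the auxin-responsive genes was lost without replicate 2 of the dark group (0.315), replicate 2 of the red group (0.0953) or either array of the red lincomycin group (0.0608). Tetrapyrrole synthesis passed as lower without replicate 1 of the dark group (0.00672) or of the red group (0.0472).

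**Figure D2:**
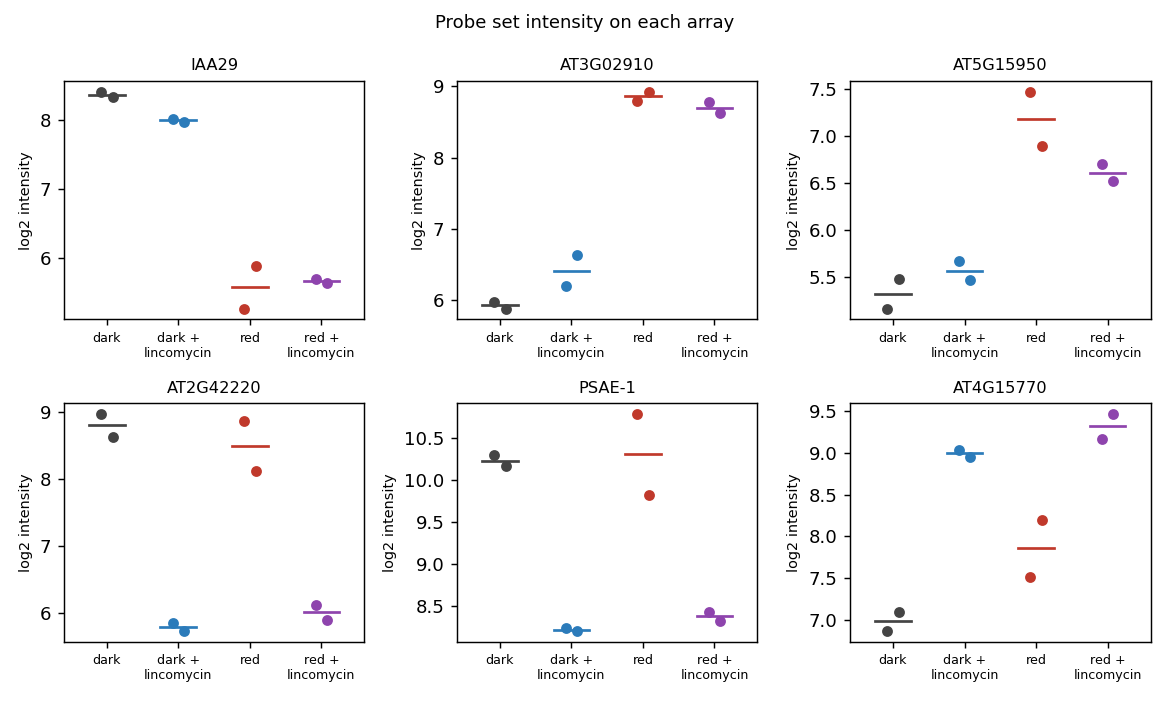
Log2 intensity of 6 named genes on each array (points, 2 per group) with the group mean (line). IAA29 and AT3G02910 were called between darkness and red light on both media, and AT5G15950 without lincomycin. PSAE-1, AT2G42220 and AT4G15770 were called for lincomycin in darkness. Without a call, AT5G15950 changed by 1.04 (log2) after red light with lincomycin. For lincomycin after red light, also without a call, PSAE-1 was at -1.92, AT2G42220 at -2.47 and AT4G15770 at 1.46. The 6 were picked for the plot after their values were seen.

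The second comparison put the same 30 min of red light to seedlings on lincomycin. IAA29 fell by 2.33 ± 0.21, a 5.02-fold decrease with adjusted p = 0.0299. AT3G02910 rose by 2.28 ± 0.18 (4.86-fold, adjusted p = 0.0239) and AT4G17670 by 1.90 ± 0.18 (3.73-fold, adjusted p = 0.0328). The PIF targets and the auxin-responsive genes, which share IAA29, fell as lists here too, although not each member did: FHL was at 0.12 and GH3.1 at 0.14. The PIF targets had a median of -0.42 (camera adjusted p = 0.000122; adjusted p = 0.0733 with an estimated correlation). IAA29 was called over all probe sets, and IAA29 and HAT2, a homeodomain transcription factor at -0.66, were lower when adjusted over the list alone. The auxin-responsive genes had a median of -0.44 (camera adjusted p = 0.000385; adjusted p = 0.0733 with an estimated correlation), with 1 member lower over all probe sets and 2, IAA29 and GH3.3 (-0.67), adjusted over the list alone.

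The other 7 tested lists did not pass after red light on lincomycin. The 76 plastid-encoded genes had a median of -0.02 (camera adjusted p = 0.425), where the same list had risen without lincomycin. The interaction of that list is given with the last comparison. The photosystem and electron transport genes were at 0.05 (0.217), tetrapyrrole synthesis at -0.02 (0.425), and plastid ribosomal proteins at 0.13 (0.217). Flavonoid and anthocyanin synthesis was at 0.07 (0.173), heat, oxidative and mitochondrial stress at 0.17 (0.508) and cell wall loosening at -0.01 (0.888). UGT78D2, a flavonoid glycosyltransferase, was at 0.96 with adjusted p = 0.565, and it was the 1 member of its list higher when adjusted over the list alone, as it was without lincomycin at 0.83 (adjusted p = 0.164). GI was at 0.11 and LHCB4.2 at 0.01, each with an adjusted p that rounds to 1.

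Red light on lincomycin gave 14 calls in limma, 13 higher and 1 lower, 3 of them with exactly 1 listed gene, and 876 probe sets with an unadjusted p under 0.05. The largest increase, 3.25, belonged to a probe set with no listed gene. Of the 14 probe sets, 11 were called in the same direction without lincomycin (10 higher, 1 lower), and all 14 had the same sign there. Independent calls would share 0.0166 and 0.000615, but both comparisons use 1 shared spread per probe set. Of the 43 calls without lincomycin, 38 (88.4%) had the same sign on lincomycin, with median changes of 3.23-fold without lincomycin and 2.65-fold with it among the 29 higher, and log2 medians of -1.25 and -0.13 among the 14 lower. Whether single probe sets differed between the media is the interaction, in which 0 passed. The count was 28 without either array of the dark group, 0 without either array of the dark lincomycin group (492 and 382 with an unadjusted p under 0.05) and 7 without either array of the red group. It was 2 and 0 without replicate 1 and replicate 2 of the red lincomycin group (407 with an unadjusted p under 0.05 for the latter). AT3G02910, AT4G17670 and IAA29 kept their calls without 4 of the 8 arrays. The number of calls shared by both media was 11 with all arrays, 3 and 24 without replicate 1 and replicate 2 of the dark group, 0 without either array of the dark lincomycin group, 0 and 1 without those of the red group, and 2 and 0 without those of the red lincomycin group. Among the lists, plastid-encoded genes passed as higher without replicate 1 of the dark lincomycin group (adjusted p = 3.03e-08) and as lower without replicate 2 of it (2.84e-15). The tetrapyrrole synthesis list passed as lower without replicate 1 of the red lincomycin group (0.0469), and photosystem and electron transport subunits, nuclear (0.0146), plastid ribosomal proteins, nuclear (0.00127) and flavonoid and anthocyanin synthesis (0.0497) as higher without replicate 2 of it.

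The third comparison asked what lincomycin did to seedlings kept in darkness. Some nuclear genes of photosynthesis fell: PSAE-1, a subunit of photosystem I, by 2.01 ± 0.28 (4.02-fold, adjusted p = 0.0406), and PSAN of the same complex by 1.08 ± 0.15 (adjusted p = 0.0395). AT1G51400, a small photosystem II protein, fell by 1.53 ± 0.24 and PRK, the phosphoribulokinase of the Calvin cycle, by 1.43 ± 0.22 (adjusted p = 0.0455). The antenna genes LHCB4.1 (-0.25), LHCB4.2 (0.18) and LHCB4.3 (-0.27) and the Calvin cycle gene RCA (-0.02) did not pass, with adjusted p of 0.519 or above. The largest decrease of a named gene was that of AT2G42220, a rhodanese-like protein, a 7.98-fold change (SE of the log2 change 0.26, adjusted p = 0.0193), followed by AT5G48490, a lipid transfer protein (-2.52), and AT5G13770 (-2.12). Among the genes that rose were AT4G15770 (2.01 ± 0.24), a homologue of a ribosome assembly factor, AT5G55140 (1.43 ± 0.17) of the ribosomal L30 family, AT5G46710 (1.76 ± 0.25), a PLATZ transcription factor, and AT4G38150 (1.56 ± 0.16), a pentatricopeptide repeat protein. ZAT10, a zinc finger repressor of stress responses, rose by 1.01 ± 0.14 (adjusted p = 0.0407).

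The remaining named increases on lincomycin in darkness were AT2G07751 (2.49), AT3G06780 (1.92), AT5G66330 (1.62), a leucine-rich repeat protein, AT5G41970 (1.62), AT5G52420 (1.45) and AT1G18850 (1.43). The remaining decreases were AT4G10060 (-1.71), AT4G37550 (-1.57), AT1G56720 (-1.52), AT5G25080 (-1.48) and AT5G53880 (-1.46). The adjusted p of the 20 genes named by size ran from 0.0171 for AT2G07751 and AT4G10060 to 0.0484. AT1G56720 and AT5G53880 were also lower after red light without lincomycin, a comparison that uses the same dark arrays.

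The nuclear photosystem and electron transport list fell on lincomycin in darkness, with a median of -0.69 over 5 members (camera adjusted p = 0.00687; adjusted p = 0.405 with an estimated correlation). Of its members, 2 were lower over all probe sets and 4 adjusted over the list alone, and PSBY was at 0.34. All 9 measured tetrapyrrole synthesis genes, the path to chlorophyll and haem, were below 0 and the list fell (median -0.55, camera adjusted p = 0.00334; adjusted p = 0.429 with an estimated correlation), with 0 called over all probe sets by limma and 2 lower adjusted over the list alone: PORB, the protochlorophyllide oxidoreductase, at -0.83 and AT1G74470, a geranylgeranyl reductase, at -0.83. Calvin cycle genes, with too few measured members for a set test, had a median of -0.87, 1 of 3 lower over all probe sets and 2 adjusted over the list alone. The 3 reference genes were all lower when adjusted over the list alone, at a median of -0.67, and 0 of them over all probe sets. AT2G28390, the SAND family gene, was at -0.61 (adjusted p = 0.114 in limma). The medians of the photosystem list (-0.69) and of tetrapyrrole synthesis (-0.55) thus do not stand apart from that of these 3 reference genes.

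Plastid-encoded genes moved in both directions on lincomycin in darkness. The list rose with a median of 0.38 (54 of 76 above 0, camera adjusted p = 0.00809; adjusted p = 0.805 with an estimated correlation), and 6 members were higher and 4 lower when adjusted over the list alone. The 1 member called over all probe sets went the other way: rps14, a plastid ribosomal protein, fell by 1.14 ± 0.18 (adjusted p = 0.0471). Of the members adjusted over the list alone, rpoA was at 1.23 while psbB, a photosystem II core protein, was at -1.43. The list's median relative to the 8-array mean was -0.61 and -0.09 on the dark arrays, the first being the array with a 41.2-fold actin ratio, and 0.52 and -0.24 on those of the dark lincomycin group.

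Lists that did not pass on lincomycin in darkness were the PIF targets (median -0.18, camera adjusted p = 0.839), with 1 member higher and 1 lower adjusted over the list alone, and the auxin-responsive genes (-0.20, 0.752). Nor did cell wall loosening (0.41, 0.298), with 2 higher adjusted over the list alone, or plastid ribosomal proteins (0.15, 0.839), with 2 lower adjusted over the list alone. Heat, oxidative and mitochondrial stress was at 0.49 (0.0656). The flavonoid and anthocyanin list was at -0.04 (0.839) and at 0.04 with array medians shifted. EXPA7 was at 1.03 (adjusted p = 0.0927) and GI at 0.92 (adjusted p = 0.0543).

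**Figure D3:**
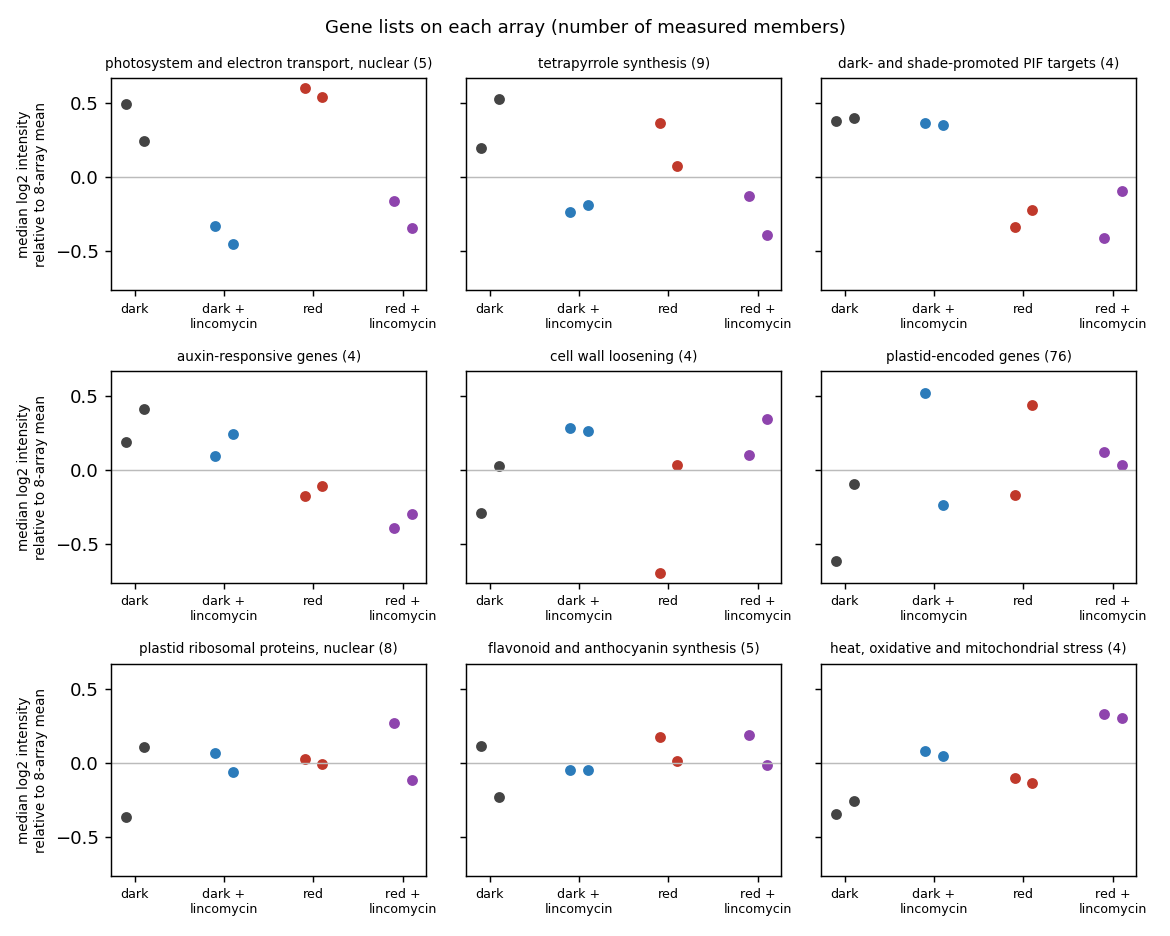
Median log2 intensity of each tested list on each array, relative to the mean of the 8 arrays (vertical axis), with 2 points per group. The plastid-encoded list lay at -0.61 and -0.09 on the dark arrays and at 0.52 and -0.24 on the dark lincomycin arrays.

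Lincomycin in darkness gave 223 calls in limma, 102 higher and 121 lower, 98 of them with exactly 1 listed gene, and 4110 probe sets with an unadjusted p under 0.05. At least a 2-fold change was seen for 78 of those higher and 93 of those lower. The share of calls that were higher was 45.7%, against 67.7% when array medians were shifted and 60.6% after quantile normalization. Without replicate 1 of the dark group, the array with the high actin ratio, 295 were called, 120 of them among the 223. Without replicate 2 of it 1950 were called, and without either array of the red group 405. Without replicate 1 or replicate 2 of the dark lincomycin group, or either array of the red lincomycin group, the count was 0 (2268, 2222 and 3344 with an unadjusted p under 0.05). Replicate 2 of the dark group also decided the list calls of photosystem and electron transport subunits, nuclear (adjusted p = 0.0555 without it) and tetrapyrrole synthesis (0.235). The call of the plastid-encoded genes was lost without replicate 1 of the dark group (0.591) or replicate 1 of the dark lincomycin group (0.807, on the lower side).

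The fourth comparison put lincomycin to seedlings after 30 min of red light. The nuclear photosystem and electron transport genes fell as a group, with a median of -0.76 and all 5 members below 0 (camera adjusted p = 8.88e-07; adjusted p = 0.0753 with an estimated correlation). No member passed over all probe sets and 4 were lower when adjusted over the list alone, PSAE-1 being at -1.92 ± 0.28 (adjusted p = 0.122). Tetrapyrrole synthesis fell with a median of -0.59 (7 of 9 below 0, camera adjusted p = 0.00773; adjusted p = 0.491 with an estimated correlation), with 0 members over all probe sets and 3 lower adjusted over the list alone, PORB being at -1.08 ± 0.17 (adjusted p = 0.138). The 4 cell wall loosening genes, expansins and xyloglucan endotransglucosylases, rose with a median of 0.52 (camera adjusted p = 0.0386; adjusted p = 0.491 with an estimated correlation), with 0 members called over all probe sets and 0 adjusted over the list alone. A wider list of 28 expansins and xyloglucan endotransglucosylases, written after the counts had been seen, did not pass (mean -0.08, 14 of 28 above 0, camera adjusted p = 0.499).

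In this comparison of lincomycin after red light, all 3 measured light-harvesting antenna genes were lower when adjusted over the list alone, and 0 over all probe sets. LHCB4.1 was at -1.04 ± 0.20 (adjusted p = 0.225), LHCB4.2 at -1.20 and LHCB4.3 at -0.63. PRK was at -0.93 (adjusted p = 0.320), the 1 of 3 Calvin cycle genes lower when adjusted over the list alone. Of the plastid-encoded genes, psbH, a photosystem II protein, was at -2.56 ± 0.49 (adjusted p = 0.225), and 3 members were lower when adjusted over the list alone and 0 over all probe sets, while the list as a whole had a median of -0.09 (camera adjusted p = 0.591). The PIF targets (median 0.06), auxin-responsive genes (-0.02), plastid ribosomal proteins (-0.02) and flavonoid and anthocyanin genes (-0.03, with a mean of 0.04) had camera adjusted p of 0.835 or above, and heat, oxidative and mitochondrial stress was at 0.38 (0.103). With quantile normalization the plastid ribosomal protein median was 0.01.

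Only 6 probe sets were called for lincomycin after red light in limma, 1 higher and 5 lower, and 1894 had an unadjusted p under 0.05. None of the 6 had a listed gene. The 1 higher changed by 1.61 and the 5 lower by -3.30 to -2.51. All 6 were called in the same direction in darkness, against 0.00448 higher and 0.0266 lower for independent calls. The calls are not independent, as both comparisons use 1 shared spread per probe set. Of the 223 calls in darkness, 173 (77.6%) had the same sign after red light, with medians of 1.22 and 0.31 among those higher and -1.21 and -0.18 among those lower. The named genes with the lowest p did not pass: AT2G42220 was at -2.47 ± 0.26 (adjusted p = 0.0594), AT5G62290 at 1.57 ± 0.17 (adjusted p = 0.0594) and AT1G52930, a Brix domain protein of ribosome assembly, at 1.26 ± 0.14 (adjusted p = 0.0620).

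The count for lincomycin after red light was 32 without either array of the dark group, 1 without either array of the dark lincomycin group, 2 and 24 without replicate 1 and replicate 2 of the red group, and 0 without either array of the red lincomycin group (862 and 1042 with an unadjusted p under 0.05). The calls shared with darkness numbered 24 and 25 without the arrays of the dark group, 0 without either of the dark lincomycin group, 2 and 19 without those of the red group and 0 without either of the red lincomycin group. Tetrapyrrole synthesis did not pass without replicate 2 of the red lincomycin group (adjusted p = 0.144), cell wall loosening did not without that array (0.172) or replicate 1 of the red group (0.483), and plastid-encoded genes passed as lower without replicate 1 of the red group (3.50e-06).

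The interaction asked whether the response to red light differed with lincomycin. In limma 0 of 22746 probe sets passed, the lowest adjusted p being 0.316, while 2359 (10.4%) had an unadjusted p under 0.05. The genes with the lowest p, which did not pass, were AT5G22280 (1.72 ± 0.19), AT1G56720 (1.48 ± 0.20) and AT2G31110 (-1.62 ± 0.22), each with adjusted p = 0.316. LHCB4.2 was at -1.37 ± 0.47 (adjusted p = 0.408), PSBY at -1.06 ± 0.23 (0.336), EXPA7 at -1.58 ± 0.35 (0.336), and ZAT10 at -0.89 ± 0.20 (0.336). When adjusted over the list alone, 2 of the 3 antenna genes, 2 of the 3 root markers, PSBY and ZAT10 were lower, and 0 over all probe sets. GI, the 1 measured member of its list, had an unadjusted p of 0.00279 and an adjusted p of 0.336.

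The plastid-encoded genes were the 1 list fixed beforehand past the threshold in the interaction, with a median of -0.35 (61 of 76 below 0, camera adjusted p = 0.00269, and 0.906 with an estimated correlation). Of their members 0 were called over all probe sets and 0 adjusted over the list alone. The interaction of their array means was 0.803 times its standard error, so a spread of the whole list between replicate arrays may account for it. The other lists fixed beforehand that were called in only some of the comparisons did not differ in the interaction by camera. The PIF targets (median 0.12), auxin-responsive genes (-0.03, with a mean of 0.07), photosystem and electron transport genes (0.08, with a mean of -0.09) and tetrapyrrole synthesis (0.12) had camera adjusted p = 0.851. So did cell wall loosening (0.12, with a mean of -0.05), plastid ribosomal proteins (-0.16), flavonoid and anthocyanin synthesis (-0.11, with a mean of 0.10) and heat, oxidative and mitochondrial stress (0.01, with a mean of -0.07). With array medians shifted, the medians of photosystem and electron transport (-0.04), tetrapyrrole synthesis (-0.01), cell wall loosening (-0.00386) and stress genes (-0.11) were below 0. That scaling moved the median interaction of all probe sets to -0.13.

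On simulated data with an equal spread in all groups, unlike the real groups, 78% of interactions of 2 (log2) and 5% of interactions of 1 were recovered. The count of 0 thus leaves room for many changes of the smaller size. Leaving out replicate 2 of the dark group gave 609 interaction calls, and leaving out each of the other 7 arrays gave 0, with 1171 to 3427 probe sets having an unadjusted p under 0.05. The call of the plastid-encoded genes was lost without replicate 1 of the dark group (adjusted p = 0.608), replicate 1 of the dark lincomycin group (0.924) or replicate 2 of the red group (0.821).

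The lists with the fewest measured members are given by values alone. Seed lipid mobilisation had medians of 0.17 and 0.05 after red light without and with lincomycin, and of 0.54 and 0.42 for lincomycin in darkness and after red light. M17, the 1 measured gene of seed storage and late embryogenesis, was at -0.67 and 0.59, and at -0.05 and 1.21, in the same order; its change in darkness was 0.03 with array medians shifted. LCYB, of carotenoid synthesis, was at 0.13, -0.05, 0.05 and -0.12, and RPOTMP, an organelle RNA polymerase, at 0.32, -0.05, 0.09 and -0.27. CPN60B2, a plastid chaperonin, was at 0.11, 0.32, 0.27 and 0.48, and HYH, a light-regulated transcription factor, at 0.13, -0.02, -0.03 (0.05 with array medians shifted) and -0.18. None of these passed over all probe sets, and CPN60B2, the 1 measured member of its list, had an unadjusted p of 0.0494 for lincomycin after red light. Touch, wound and rapid stress had medians of -0.03, 0.05, 0.00 and 0.12, of which those after red light without lincomycin and for lincomycin in darkness changed sign with another scaling. No member was measured of the lists of photoreceptors and core light signalling and of dark and sugar starvation.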

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

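The tests of explanations in this part, and the bounds of the tests on list means, were chosen after the results were seen, and so were the lists on seed maturation, cold and dehydration, expansins and mitochondria-encoded genes, whose genes' values had not been seen except for nad4L, a mitochondria-encoded gene.

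The seed maturation genes, late embryogenesis and seed storage processing genes among them, differed in their response to red light between the media by the interaction test, with a median of 1.04, 9 of 9 members above 0 and camera adjusted p = 2.72e-06 (adjusted p = 0.174 with an estimated correlation). They fell after red light without lincomycin (-0.65) and rose with it (0.59), and 5 members, LEA18 at 1.66 ± 0.30 first among them, passed adjusted over the list alone while 0 did over all probe sets in limma. The 2 arrays with aberrant control probe sets stay open as a cause: without both, the median was 0.60 (8 of 9 above 0, camera adjusted p = 0.000153), but the array means then differed by 3.04 standard errors, not past the two-sided point of t for 1 list, with 1 array left in each group without lincomycin. A spread of the whole list between replicate arrays may be the source and stays open too, since with all 8 arrays the array means differed by 3.61 standard errors, between the points of 2.78 for 1 list and 6.93 for 22 lists. A biological difference in the light response with lincomycin, which the design names, also stays open, untested beyond these arrays.

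The plastid-encoded genes differed in their response to red light between the media, with a median of -0.35 and 61 of 76 members below 0 (camera adjusted p = 0.00269; adjusted p = 0.906 with an estimated correlation). The 2 arrays with aberrant control probe sets stay open as a cause: without both the median was -0.59 (camera adjusted p = 5.45e-05), but the array means then differed by 0.767 standard errors. A spread of the whole list between replicate arrays may account for the difference, as the interaction of the array means was 0.803 times its standard error and the array means of the dark lincomycin replicates lay 0.781 apart. The call was lost without replicate 1 of the dark group (adjusted p = 0.608), replicate 1 of the dark lincomycin group (0.924) or replicate 2 of the red group (0.821). An effect of lincomycin on how plastid transcripts respond to light stays possible and was not tested apart from this.

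The cold and dehydration genes, which share LEA18 and LEA4-5 with the seed maturation list, differed between the media in the interaction test by a median of 0.65 (11 of 11 above 0, camera adjusted p = 0.000431; adjusted p = 0.174 with an estimated correlation; array means 5.55 standard errors apart). The mitochondria-encoded genes differed by -0.25 (13 of 15 below 0, camera adjusted p = 0.00288; adjusted p = 0.387 with an estimated correlation; array means 1.98 standard errors apart, under 2.78), a call lost without replicate 2 of the dark group (0.195) or replicate 2 of the red group (0.0634). The expansins and xyloglucan endotransglucosylases (wider list) differed by -0.15 (18 of 28 below 0, camera adjusted p = 0.0466; adjusted p = 0.220 with an estimated correlation; array means 2.56 standard errors apart, under 2.78), a call lost without replicate 1 of the dark group (0.119), replicate 2 of the dark lincomycin group (0.154), either array of the red group (0.0757 and 0.107) or replicate 1 of the red lincomycin group (0.0526).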

How the results depend on the processing

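Array quality weights, leaving out the 2 arrays with aberrant control probe sets and the added lists were chosen after the results were seen, and the other settings were planned. The counts are given in the order red light without lincomycin (43 with all arrays), red light with it (14), lincomycin in darkness (223), lincomycin after red light (6), both light comparisons (11) and both lincomycin comparisons (6), where they moved by over 1.5 times. The cause was not tested, except where the construction shows it.

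Shifting array medians gave 96 for red light without lincomycin, 341 for lincomycin in darkness, 18 for lincomycin after red light, and 17 and 15 for the shared calls, and quantile normalization 1 for lincomycin after red light and 1 for both lincomycin comparisons. Leaving out the dimmest 30% gave 26 and 19 for these last counts, where fewer probe sets were tested, and trend with robust fitting 108 for lincomycin in darkness, 21 after red light and 16 shared. Raising low values gave 28, 0 (1129 with an unadjusted p under 0.05 in limma), 124, 0 (1884), 0 and 0. The replicate block gave 7, 1, 4, 1, 1 and 1, and the labels do not say that the numbers pair samples. The deviations of replicate 1 correlated between groups at -0.33 to 0.44 across probe sets, the 0.44 between the dark and red groups, where each dark array correlated best with the red array of its number (0.9704, against 0.9700 for its own replicate, and 0.983), while the red arrays correlated best with red replicate 2 (0.979) and red lincomycin replicate 1 (0.990). Only the 4 arrays of each comparison gave 0 (1549), 150 and 0 (3571) for the first 3, and 0 and 0 shared. Array weights, 0.435 to 0.560 without lincomycin and 1.87 to 2.19 with it, gave 4, 155, 122, 31, 4 and 21.

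Without the 2 arrays with aberrant control probe sets the counts were 949, 150, 3746, 90, 69 and 71, where by construction the spread came from the lincomycin groups alone. Leaving out each array in turn gave 0 to 1219, 0 to 28, 0 to 1950, 0 to 32, 0 to 24 and 0 to 25, and 0 to 609 for the interaction. The lists past the threshold numbered 0 in all 5 comparisons with an estimated correlation. Leaving out arrays gave 1 to 4, 2 to 5, 1 to 3, 1 to 3 and, for the interaction, 0 to 1, and without the 2 arrays the interaction had 2. The added lists gave 5 for lincomycin in darkness and 4 for the interaction.

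Genes named by size had no overlap between the arrays compared, so leaving out an array could not reverse them. Trend with robust fitting, the block, only 4 arrays, array weights and the 2-fold requirement leave each change as it was. Of the 41 calls of named genes, 0 reversed in any setting, which adds little for that reason. They kept their calls in 39 cases with shifted medians, 33 with quantile normalization, 36 without the dimmest 30%, 11 with low values raised, 28 with trend and robust fitting, 3 with the block, 3 with only 4 arrays, 27 with array weights, 41 without the 2 arrays and 38 with a 2-fold change, and in 1 to 41 with each array left out. Signal over background limits what could be seen for the 6823 probe sets in the dimmest 30% and for values under a log2 intensity of 3.51, where a change is hard to measure.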

Other observations

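The lists and genes in this part, the tests of explanations and the comparisons of 4 arrays with 4 were chosen after the counts per comparison were seen, while the tests on other splits of the arrays were written before their results were seen.

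Over a wider list of 39 nuclear photosynthesis and thylakoid genes, transcripts fell with lincomycin in darkness (median -0.24, camera adjusted p = 0.000202; adjusted p = 0.242 with an estimated correlation) and after red light (-0.44, 5.19e-06; adjusted p = 0.518 with an estimated correlation), with 3 lower over all probe sets in darkness and 10 adjusted over the list alone, and 14 adjusted over the list alone after red light. Mitochondria-encoded genes (15) rose on lincomycin in darkness (0.31, 0.000109; adjusted p = 0.242 with an estimated correlation), with 1 higher over all probe sets, the cytochrome maturation gene ccb452 at 2.64-fold (adjusted p = 0.0406), and 7 adjusted over the list alone. They also rose after red light without lincomycin (0.22, 0.00397; adjusted p = 0.416 with an estimated correlation), a call lost without replicate 2 of the dark group (0.173) or of the red group (0.0525). Both rises are against the dark group, whose replicates, 1 of them the array with the 41.2-fold actin ratio, lay furthest apart in the list's mean (0.398). UDP-glycosyltransferases rose on lincomycin in darkness (0.11, 0.0190; adjusted p = 0.424 with an estimated correlation), UGT85A4 by 0.96 (adjusted p = 0.0484), and the list did not pass without replicate 1 of the dark group (0.320).

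The seed maturation (wider list) genes fell after red light without lincomycin (median -0.65, 9 of 9 below 0, camera adjusted p = 0.00623; adjusted p = 0.416 with an estimated correlation) and with lincomycin in darkness (-0.65, 9 of 9, 0.000451; adjusted p = 0.242 with an estimated correlation). They rose after red light on lincomycin (0.59, 8 of 9 above 0, 1.53e-05, and adjusted p = 0.205 with an estimated correlation) and with lincomycin after red light (0.39, 0.0177, and adjusted p = 0.518 with an estimated correlation). Both falls are against the dark group, whose replicate 1 had the high actin ratio, and both rises use the red lincomycin arrays. The falls are thus not independent of each other, nor are the rises. The fall after red light was lost without either array of the dark group (0.0998 and 0.0521) or replicate 1 of the red group (0.179), and the rise with lincomycin after red light without replicate 1 of the red group (0.193) or of the red lincomycin group (0.0916). Cold and dehydration genes rose after red light on lincomycin (0.30, 11 of 11 above 0, 3.45e-05; adjusted p = 0.194 with an estimated correlation) and fell with lincomycin in darkness (-0.39, 0.0201; adjusted p = 0.242 with an estimated correlation; 0.0757 without replicate 1 of the dark group). The auxin synthesis, Aux/IAA, GH3 and LBD (wider list) genes fell as a list after red light on lincomycin (-0.08, 0.0383; adjusted p = 0.205 with an estimated correlation), with IAA29 as the 1 of 18 members lower, both over all probe sets and adjusted over the list alone. This call was lost without either array of the dark group (0.0578), replicate 2 of the dark lincomycin group (0.215) or replicate 2 of the red lincomycin group (0.0909).

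The other added lists passed in 0 comparisons by camera, organelle RNA processing coming nearest with lincomycin after red light (0.10, adjusted p = 0.0508) and in the interaction (0.26, 0.0518). Glutathione S-transferases had medians of 0.18 after red light on lincomycin and -0.21 with lincomycin in darkness, endoplasmic reticulum protein folding 0.11 and -0.05, root-expressed genes 0.03 and -0.13, rapid stress genes of the wider list 0.02 and 0.00, and flavonoid genes of the wider list -0.04 and 0.00. The values of -0.05 for protein folding, 0.03 for root-expressed genes and 0.02 for rapid stress genes changed sign with array medians shifted. Of the rapid stress genes, ZAT10 (1.01) and WRKY22 (0.87, adjusted p = 0.0499) rose on lincomycin in darkness. Of the root-expressed genes, UPB1, a transcription factor, fell by 1.44 there (adjusted p = 0.0484).

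The spread of list means between replicate arrays was set against each change for all 22 lists, a test chosen after the results were seen, and it does not compare a list with other genes. Past the point of 6.93 for 22 lists lay the heat, oxidative and mitochondrial stress genes, which did not pass by camera, with lincomycin in darkness (mean 0.43, 9.54 standard errors) and after red light (0.36, 8.03). Of the 22 genes of that list only HSP23.5, AT12CYS-2, NDB2 and UPOX were measured, and AT12CYS-2 was at 0.05 and -0.05. The other changes past that point were those of the auxin-responsive genes after red light without and with lincomycin (10.6 and 9.76 standard errors), the PIF targets after red light without lincomycin (7.22) and the photosystem and electron transport genes with lincomycin after red light (7.67). The auxin-responsive genes and PIF targets, of 4 members each, share IAA29, whose change of -2.80 without and -2.33 with lincomycin makes up most of their mean changes, while GH3.1 (0.17) and XTH33 (0.10) were above 0 without lincomycin. Of the 28 list calls by camera, these 4 lay past that point. Another 11 lay between it and the point of 2.78 for 1 list, and 13 lay under 2.78. The point of 6.93 allows for 22 lists in a single comparison, but the changes past it were picked across all comparisons. The replicate spread of whole lists is thus not excluded for the 11 or the 13, nor by that point alone for the 4. Under 2.78 were the plastid-encoded genes after red light without lincomycin (1.00 standard errors), with lincomycin in darkness (1.12) and in the interaction (0.803), tetrapyrrole synthesis with lincomycin in darkness (2.58) and after red light (2.05), and cell wall loosening after red light (a change of 0.45 with a standard error of 0.32). The added lists under it were UDP-glycosyltransferases in darkness (1.09), mitochondria-encoded genes after red light without lincomycin (2.55) and in the interaction (1.98), expansins in the interaction (2.56), and seed maturation after red light without (2.41) and with lincomycin (2.70) and with lincomycin after red light (2.07).

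Between the 4 arrays with and the 4 without lincomycin, limma called 134 probe sets, 61 higher and 73 lower. AT2G04050, a transporter of the MATE efflux family, rose by 2.26 and AT4G15770 by 1.74, while AT2G42220 fell by 2.73 (adjusted p = 0.000967). Lower as well were AT5G48490 (-2.37), PSAE-1 (-1.97, adjusted p = 0.00284) and the plastid gene psbB (-1.39, adjusted p = 0.0111). Of the 35 splits of the 8 arrays, 1 gave as many calls, the real one, a share under 0.05. This count cannot exclude chance. Most other splits put replicate arrays on opposite sides, and nothing says that the replicates came from separate cultures. Both arrays with aberrant control probe sets also lie on the side without lincomycin. The highest other count was 46, from the split by light. Between the 4 arrays after red light and the 4 in darkness 46 were called, 36 higher and 10 lower, with AT3G02910 at 2.60 and IAA29 at -2.56 (adjusted p = 0.000763). Of the 35 splits 2 gave as many, so chance cannot be excluded by this count, although the other was the split by lincomycin, with 134. The light comparisons without and with lincomycin share no arrays. Of the 43 calls without lincomycin, 38 (88.4%) had the same sign with it, against 46.2% of all probe sets. All 14 calls with lincomycin had the same sign without it. Among the higher calls without lincomycin, the median change was 3.23-fold without it and 2.65-fold with it. Among the lower calls it was -1.25 and -0.13 (log2), and only IAA29 was called as lower on both media. These values argue against chance for the higher calls and IAA29, although probe sets are not independent. They do not for the other lower calls.

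Lincomycin gave 223 calls in darkness and 6 after red light, while the interaction gave 0 in limma (2359 with an unadjusted p under 0.05). Degraded RNA on replicate 1 of the dark group stays open as a cause. Counts without that array cannot decide it, since leaving the array out also changes the pooled spread. Without it all 223 changes in darkness kept their sign, with a median size 0.968 times that with all arrays. The 223 had been called with that array in the fit. All 223 also kept their sign without replicate 2 of the dark group, at 1.03 times the size. The kept signs therefore do not decide it either. The use of 1 shared spread for groups of unequal spread was not decided: with only the 4 arrays of each comparison, which leaves every change as it was and fewer degrees of freedom, the counts were 0 in darkness and 4 after red light, but 3571 and 1983 had an unadjusted p under 0.05. A larger effect of lincomycin in darkness stays open, and the interaction test did not show it for single probe sets.

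Red light without lincomycin and lincomycin in darkness shared 9 calls in the same direction, 2 higher and 7 lower, and 1 in opposite directions, where independent lists would share 0.130 higher and 0.0745 lower. Part of that excess may come from the shared dark arrays. Sharing them alone makes changes go together: across probe sets, which are not independent, r was 0.712 against 0.721 in 100 simulated draws, and 75.7% had the same sign against 73.8%. The covariance was 0.116 against 0.0729 in the draws, which already hold the shared arrays, a difference of 0.0433. Leaving out replicate 1 of the dark group gave 3 calls for red light without lincomycin and 295 for lincomycin in darkness.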
